A study of Mus musculus with 19 samples.

How the data were processed

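RNA-seq was measured in 19 mouse retina libraries, which the labels place in 6 groups: sorted cells 48 h after electroporation (3 Gfp, 3 Pou3f1), sorted cells at 14 days (4 Gfp, 5 Pou3f1) and whole retinas at E17.5 (2 heterozygous, 2 knockout). Each of the 3 files holds 1 comparison already made by the authors, with 1 line per gene and no values per library. Per the labels, the authors' tools were Salmon, DESeq2 and MACS2 with the mm10 genome build. Their versions, the annotation, the design formula and the libraries in each fit are not given in the sources used here.

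The log2 fold changes and their SE were deposited by the authors, and the fold changes are shrunken toward 0. The p-values of the overexpression tables were computed by the authors as two-sided normal p of the fold change over its SE, and in all 3 tables the adjusted p by Benjamini-Hochberg over the genes above an abundance limit. The Wald score in the overexpression tables is, per the file headers and as checked on the values, the log2 fold change over its SE. The signal in the overexpression tables is the authors' mean normalized count, that is counts divided by size factors and averaged over the libraries of a comparison. The E17.5 table holds a log2 fold change, a p-value and an adjusted p only. Checked on the values, the recomputed Wald score differed from the listed score by at most 4.45e-07, and the recomputed adjusted p from the listed adjusted p by at most 5.60e-06.

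Genes listed numbered 22294 at 48 h, 23635 at 14 days and 35734 at E17.5, of which 14714, 17789 and 14821 have an adjusted p. Gene identifiers were found in the GENCODE mouse release 21 annotation for 99.6%, 99.6% and 99.2% of them. The headers of the overexpression tables name no direction either, and a positive fold change was read as higher in Pou3f1 cells because Pou3f1 is then higher. The E17.5 table was read as knockout over heterozygote because Pou3f1 is then lower, although its file name puts the heterozygote first. That name also gives another embryonic day than the sample labels, whose age is used here.

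A gene was called at the authors' adjusted p under 0.05, and no test of fold changes per gene was added within a table. The 27 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested on the Wald score with limma 3.58.1 (cameraPR, inter-gene correlation preset to 0.01, two-sided, lists of at least 3 genes), with Benjamini-Hochberg adjustment over the lists of a comparison. For E17.5 the signed normal quantile of the p-value took the place of the score, with 2 p-values of 0 set to a very small value. Adjustment over the list alone means Benjamini-Hochberg over the p-values of a list's members. The 48 h and 14 day fold changes were compared per gene by a two-sided z test on their difference with the SE of both, and lists by cameraPR on that z. Overlaps of calls were tested by Fisher's exact test over genes with an adjusted p in both tables, with Benjamini-Hochberg adjustment over all 12 overlaps of a setting.

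Genes named in a comparison are Pou3f1, up to 10 with the largest rise and 10 with the largest fall among called genes with a mean count at or above the median (for E17.5 among all called genes), up to 4 per list by adjusted p, and up to 8 per overlap. Genes with predicted names (numbered Gm, Rik, -ps, or no symbol) were left out of the largest changes, while other pseudogenes such as Rpl32l were not. Prdm1 and Grik3 at 14 days and Isl2 at E17.5 were named after their values were seen. Some genes that the rule names are not reported here. Alternatives were an adjusted p under 0.01, a 2-fold limit, adjustment over all genes, mean count limits of 5 and 10, a correlation preset of 0.05, ranks, and 10000 random lists matched on mean count in 20 bins (unmatched at E17.5). Added after the data were seen were removal of trends with transcript length and GC content, lists without Pou3f1, calls without pseudogenes, E17.5 lists with adjusted p only, overlaps without mitochondrially encoded genes, alone or with pseudogenes, and Pou3f1 adjusted over all genes. Pseudogenes were matched to parent genes with BLAST 2.17.0 (expect limit 1e-10, at least 80% identity over at least 50% of the pseudogene).

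Tests ran on data simulated from shrunken SE or p-values, 200 genes changed per table, which may overstate detection. A true log2 change of 1 was called in 81% at 48 h, 82% at 14 days and 100% at E17.5. A change of 0.5 was called in 20%, 40% and 77%. Calls among unchanged genes made up 7.34%, 3.17% and 6.35% of calls. In each comparison 5 of 5 lists of 20 genes shifted by 2 in the statistic were called, and 0 of 15 unshifted. Smaller shifts or correlated genes were not tried. Scripts used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.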

Results

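RNA-seq of the mouse retina (19 libraries in 6 groups) was described for 3 comparisons of Pou3f1, which encodes a POU family transcription factor. In the overexpression experiment, plasmids were electroporated into the eyes of CD1 pups on postnatal day 1. Fluorescent cells carrying a control Gfp plasmid or a Pou3f1 plasmid were then sorted and combined to 150000 cells per replicate. The 48 h groups held 3 Gfp and 3 Pou3f1 libraries, and the late groups 4 Gfp and 5 Pou3f1 libraries. The late groups are called 14 days here, since the sample labels give 14 days after electroporation while the protocol text gives postnatal day 14. In the loss-of-function experiment, whole retinas of C57B6J embryos at E17.5 were compared between 2 heterozygous and 2 homozygous knockout libraries. The series concerns the genes that send axons of retinal ganglion cells to the opposite side of the brain (contralateral projections).

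The values are the authors' own log2 fold changes and p-values per gene. None of the 3 tables lists values per library, so the depth of single libraries is unknown. Mean normalized counts of all listed genes summed to 16020800 at 48 h and to 38507500 at 14 days, while the E17.5 table gives no abundance. Among genes with an adjusted p, the median standard error (SE) of the log2 fold change was 0.199 at 48 h and 0.150 at 14 days, so the 14 day table resolves smaller changes. Sorted replicates are pools of cells, and where the labels do not name separate animals the p-values measure only the spread between these samples. A gene is said to have risen or fallen only where its adjusted p was under 0.05.

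The 48 h comparison asks which genes respond soon after Pou3f1 is added to cells of the newborn retina. Single genes that rose in the Pou3f1 cells included those of the adhesion proteins Slitrk5 and Alcam and of the transcription factors Eomes and Ebf3. Genes of photoreceptor precursors, glia, synapses and blood vessels moved down as groups. Pou3f1 itself rose by 0.91 ± 0.26 on the log2 scale, or 1.87-fold, at a mean count of 37279 in the authors' deposited table (adjusted p = 0.0233). This shrunken value may understate the overexpression. At 14 days the fold change was larger at a lower mean count. Of 14714 genes with an adjusted p, 447 changed, 218 higher and 229 lower. At least 2-fold changes numbered 76 higher and 30 lower.

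Slitrk5 and Alcam, which encode surface proteins of neurons, were among the strongest rises. The authors' deposited table gives log2 fold changes (± SE) of 1.66 ± 0.21 for Slitrk5 and 1.67 ± 0.26 for Alcam (adjusted p between 1.66e-12 and 1.58e-07). Slitrk5 acts in neurites and synapses, and Alcam in growing axons. The transcription factor genes Ebf3 (1.13 ± 0.24), Eomes (1.34 ± 0.24) and Ebf1 (0.89 ± 0.20) rose as well in the authors' deposited table (adjusted p between 1.35e-05 and 0.000823). The mitochondrial genome encodes mt-Co3 (1.27 ± 0.19) and mt-Nd1 (1.04 ± 0.18), which make subunits of the respiratory chain and rose in the authors' deposited table (adjusted p between 1.08e-08 and 3.45e-06). Slc8a2 encodes a sodium-calcium exchanger, Dock11 a Cdc42 activator and Sdc1 a proteoglycan. With Plxdc2 and Fstl5 they were among the largest rises of genes with a mean count at or above the median, Slc8a2 (1.24 ± 0.23), Dock11 (1.22 ± 0.18), Plxdc2 (1.05 ± 0.18), Fstl5 (1.01 ± 0.26) and Sdc1 (0.996 ± 0.17) in the authors' deposited table (adjusted p between 1.08e-08 and 0.00735).

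The largest fall of such genes was that of Ass1, an enzyme of arginine synthesis and the urea cycle, at -1.43 ± 0.19 in the authors' deposited table (adjusted p = 2.50e-11). Pla2g7 encodes a secreted enzyme, Rasgrf2 a Ras activator, Synm an intermediate filament protein and Grik3 a kainate receptor. They fell next, Pla2g7 (-1.37 ± 0.26), Rasgrf2 (-1.29 ± 0.27), Synm (-1.19 ± 0.21) and Grik3 (-1.13 ± 0.19) in the authors' deposited table (adjusted p between 1.22e-06 and 0.000360).

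Of 27 gene lists fixed beforehand, 11 passed limma's cameraPR test at 48 h, all of them downward. Of 9 photoreceptor precursor genes with a p-value, 0 rose, 3 fell and 6 did not pass (0 rose and 3 fell adjusted over the list alone). Photoreceptor precursor genes had a median log2 fold change of -0.56 (limma cameraPR, adjusted p = 7.32e-05). Transcription factors that direct cells to the photoreceptor fate made up these 3, Prdm1 (-0.75 ± 0.17), Crx (-0.74 ± 0.22) and Neurod1 (-0.59 ± 0.18) in the authors' deposited table (adjusted p between 0.00182 and 0.0458). Of 6 rod genes with a p-value, 0 rose, 0 fell and 6 did not pass (0 rose and 0 fell adjusted over the list alone, and 0 higher and 4 lower at an unadjusted p under 0.05). Rod genes had a median log2 fold change of -0.57 (limma cameraPR, adjusted p = 0.000646). Of the 24 rod genes fixed beforehand, 18 are not listed in the 48 h table, so its rod result covers 6 genes. Of 10 cone genes with a p-value, 0 rose, 1 fell and 9 did not pass (0 rose and 1 fell adjusted over the list alone). Cone genes had a median log2 fold change of -0.22 (limma cameraPR, adjusted p = 0.0183, or 0.0568 with the correlation preset to 0.05). The cone gene that fell was Thrb, a thyroid hormone receptor, at -0.86 ± 0.25 in the authors' deposited table (adjusted p = 0.0266). Of 13 bipolar cell genes with a p-value, 0 rose, 1 fell and 12 did not pass (1 rose and 2 fell adjusted over the list alone). Bipolar cell genes had a median log2 fold change of -0.31 (limma cameraPR, adjusted p = 0.00494). Lrit3, which acts at the synapse between photoreceptors and bipolar cells, was the gene that fell, at -0.94 ± 0.28 in the authors' deposited table (adjusted p = 0.0317).

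Glial, progenitor and cell cycle genes moved the same way. Of 15 Müller glia genes with a p-value, 1 rose, 0 fell and 14 did not pass (2 rose and 9 fell adjusted over the list alone). Müller glia genes had a median log2 fold change of -0.35 (limma cameraPR, adjusted p = 0.000457). Against the direction of its list, the thyroid hormone binding protein gene Crym rose by 0.57 ± 0.17 in the authors' deposited table (adjusted p = 0.0270). Of 19 retinal progenitor genes with a p-value, 0 rose, 2 fell and 17 did not pass (1 rose and 3 fell adjusted over the list alone). Retinal progenitor genes had a median log2 fold change of -0.15 (limma cameraPR, adjusted p = 0.0257, or 0.107 with the correlation preset to 0.05). Of 16 neurogenic progenitor genes with a p-value, 0 rose, 1 fell and 15 did not pass (0 rose and 4 fell adjusted over the list alone). Neurogenic progenitor genes had a median log2 fold change of -0.20 (limma cameraPR, adjusted p = 0.00494). Atoh7, needed for the ganglion cell fate, was the neurogenic gene that fell, and Id3 and Notch1 the progenitor genes. The authors' deposited table gives -0.89 ± 0.25 for Atoh7, -0.60 ± 0.16 for Id3 and -0.53 ± 0.15 for Notch1 (adjusted p between 0.0103 and 0.0191). Of 30 cell cycle genes with a p-value, 0 rose, 1 fell and 29 did not pass (0 rose and 1 fell adjusted over the list alone). Cell cycle genes had a median log2 fold change of -0.20 (limma cameraPR, adjusted p = 0.00494, or 0.0582 with the correlation preset to 0.05). The kinetochore gene Cenpf fell, at -0.72 ± 0.17 in the authors' deposited table (adjusted p = 0.00230).

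Of 25 synapse genes with a p-value, 1 rose, 4 fell and 20 did not pass (2 rose and 7 fell adjusted over the list alone). Synapse genes had a median log2 fold change of -0.36 (limma cameraPR, adjusted p = 0.000223). Genes that fell included Nrxn3 (-0.98 ± 0.22), Cplx3 (-0.81 ± 0.20) and Sv2b (-0.86 ± 0.24) in the authors' deposited table (adjusted p between 0.000715 and 0.0191). Of 14 immediate early and stress genes with a p-value, 0 rose, 0 fell and 14 did not pass (0 rose and 0 fell adjusted over the list alone, and 0 higher and 3 lower at an unadjusted p under 0.05). Immediate early and stress genes had a median log2 fold change of -0.24 (limma cameraPR, adjusted p = 0.00494). Markers of blood vessels, cells outside the retinal lineage, moved down beside these groups. Of 12 blood vessel genes with a p-value, 0 rose, 1 fell and 11 did not pass (0 rose and 3 fell adjusted over the list alone). Blood vessel genes had a median log2 fold change of -0.37 (limma cameraPR, adjusted p = 0.000383). Kdr, a growth factor receptor, was the vessel gene that fell, at -0.63 ± 0.15 in the authors' deposited table (adjusted p = 0.00298).

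The other 16 lists did not pass at 48 h (limma cameraPR). Of 11 POU family genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.576). Of 37 ganglion cell transcription factors 3 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of -0.04 (adjusted p = 0.607). Of 30 ganglion cell structure genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of -0.14 (adjusted p = 0.0704). Of 13 contralateral genes 2 rose and 0 fell (2 and 1 adjusted over the list alone), with a median of -0.02 (adjusted p = 0.638). Of 8 ipsilateral genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.329). Of 60 axon guidance genes 2 rose and 5 fell (4 and 7 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.0770). Members that passed besides those named included Pou6f1, the axonal adhesion gene Cntn2, which is contralateral, and the guidance genes Ephb1, Sema5a and Plxna2. Their values were 0.58 ± 0.17 for Pou6f1, 1.07 ± 0.27 for Cntn2, -0.83 ± 0.16 for Ephb1, -0.92 ± 0.19 for Sema5a and -0.84 ± 0.18 for Plxna2 in the authors' deposited table (adjusted p between 5.59e-05 and 0.0223). Ephb1, the receptor that turns axons away at the midline, is also the ipsilateral gene that fell. Ganglion cell genes that fell were Atoh7, Irx6 (-0.83 ± 0.22) and Jam2 (-0.49 ± 0.15) in the authors' deposited table (adjusted p between 0.0106 and 0.0438).

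Of 18 amacrine genes 1 rose and 0 fell (1 and 1 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.0717). Of 8 horizontal cell genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 1 and 1 at an unadjusted p under 0.05), with a median of -0.21 (adjusted p = 0.298). Of 15 interferon genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05), with a median of 0.02 (adjusted p = 0.645). Of 14 p53 and cell death genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 1 at an unadjusted p under 0.05), with a median of -0.05 (adjusted p = 0.720). Of 11 pigment epithelium genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of -0.01 (adjusted p = 0.663). Of 15 lens genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05), with a median of -0.02 (adjusted p = 0.787). Of 12 microglia genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 1 at an unadjusted p under 0.05), with a median of -0.19 (adjusted p = 0.0717). Of 7 red blood cell genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05), with a median of -0.04 (adjusted p = 0.645). Of 9 astrocyte and oligodendrocyte genes 0 rose and 0 fell (0 and 1 adjusted over the list alone and 0 and 1 at an unadjusted p under 0.05), with a median of -0.20 (adjusted p = 0.0592). Of 4 sex-linked genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05), with a median of -0.20 (adjusted p = 0.645). The amacrine gene that rose was the neuropeptide gene Npy and the pigment epithelium gene was the chloride channel gene Best1, with 0.94 ± 0.19 for Npy and 1.398 ± 0.29 for Best1 in the authors' deposited table (adjusted p between 0.000242 and 0.000361). The median was negative while mean and test pointed up for the POU, ganglion cell transcription factor, contralateral and pigment epithelium lists. For the ipsilateral list the median was positive while mean and test pointed down.

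The 14 day comparison asks what the same overexpression does once the retina has formed. Ganglion cell transcription factor, axon guidance and contralateral genes, led by Pou4f2, Eomes and Ebf3, were higher in Pou3f1 cells than in Gfp cells, and rod, cone and Müller glia genes were lower. Interferon and microglia genes were also higher. Pou3f1 itself had a log2 fold change of 5.57 ± 0.27, or 47.6-fold, at a mean count of 16972 in the authors' deposited table (adjusted p = 3.40e-88). Of 17789 genes with an adjusted p, 3690 changed, 2051 higher and 1639 lower. Changes of at least 2-fold numbered 430 higher and 66 lower.

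Of 37 ganglion cell transcription factors with a p-value, 16 rose, 0 fell and 21 did not pass (17 rose and 0 fell adjusted over the list alone). Ganglion cell transcription factors had a median log2 fold change of 0.33 (limma cameraPR, adjusted p = 5.39e-16). Pou4f2, which drives ganglion cell differentiation, Eomes, Ebf3 and Irx3 had the smallest adjusted p. The authors' deposited table gives log2 fold changes of 3.64 ± 0.26 for Pou4f2, 3.07 ± 0.26 for Eomes, 2.68 ± 0.24 for Ebf3 and 1.33 ± 0.14 for Irx3 (adjusted p between 7.86e-40 and 5.59e-19). Of 11 POU family genes with a p-value, 4 rose, 0 fell and 7 did not pass (5 rose and 0 fell adjusted over the list alone). POU family genes had a median log2 fold change of 0.28 (limma cameraPR, adjusted p = 5.75e-13). Besides Pou3f1 and Pou4f2, Pou3f2 (1.43 ± 0.20) and Pou3f4 (1.10 ± 0.28) rose in the authors' deposited table (adjusted p between 3.28e-10 and 0.00124). Without Pou3f1 in the list, an alternative added after the data were seen, the POU family and the contralateral list still passed (limma cameraPR, adjusted p = 1.19e-05 and 5.45e-09).

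Of 13 contralateral genes with a p-value, 8 rose, 0 fell and 5 did not pass (9 rose and 0 fell adjusted over the list alone). Contralateral genes had a median log2 fold change of 0.99 (limma cameraPR, adjusted p = 7.11e-17). Pou3f1, Sox4 and Cntn2 are also in the POU, ganglion cell factor and guidance lists, so these lists are not independent. After Pou3f1, the adhesion gene Cntn2 and the transcription factors Sox4 and Lhx9 led that list, with 1.47 ± 0.19 for Cntn2, 1.37 ± 0.18 for Sox4 and 1.71 ± 0.28 for Lhx9 in the authors' deposited table (adjusted p between 7.03e-12 and 9.63e-08). Of 60 axon guidance genes with a p-value, 32 rose, 3 fell and 25 did not pass (32 rose and 3 fell adjusted over the list alone). Axon guidance genes had a median log2 fold change of 0.45 (limma cameraPR, adjusted p = 2.88e-13). Epha3 encodes an ephrin receptor, Dcc a netrin receptor and Robo1 a Slit receptor. With Cntn2 they had the smallest adjusted p of the list, Epha3 (0.91 ± 0.10), Dcc (0.79 ± 0.11) and Robo1 (1.59 ± 0.23) in the authors' deposited table (adjusted p between 8.99e-16 and 1.25e-09). Of 18 amacrine genes with a p-value, 3 rose, 0 fell and 15 did not pass (3 rose and 0 fell adjusted over the list alone). Amacrine genes had a median log2 fold change of 0.38 (limma cameraPR, adjusted p = 0.00527). Gad2 and Gad1 make the transmitter GABA, Tfap2c is an AP-2 factor, and these 3 rose, Gad2 (1.21 ± 0.23), Gad1 (0.82 ± 0.26) and Tfap2c (0.92 ± 0.27) in the authors' deposited table (adjusted p between 9.35e-06 and 0.0123).

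Of 16 neurogenic progenitor genes with a p-value, 6 rose, 0 fell and 10 did not pass (6 rose and 0 fell adjusted over the list alone). Neurogenic progenitor genes had a median log2 fold change of 0.26 (limma cameraPR, adjusted p = 0.00181). The Notch ligand gene Dll3 and the transcription factor gene Olig2 were among those that rose. The authors' deposited table gives 1.39 ± 0.29 for Dll3 and 1.299 ± 0.29 for Olig2 (adjusted p between 5.62e-05 and 0.000222). Of 30 cell cycle genes with a p-value, 7 rose, 0 fell and 23 did not pass (8 rose and 0 fell adjusted over the list alone). Cell cycle genes had a median log2 fold change of 0.38 (limma cameraPR, adjusted p = 0.00606, or 0.0618 with the correlation preset to 0.05). Helicase subunits of DNA replication had the smallest adjusted p, Mcm7 (0.42 ± 0.10), Mcm6 (0.82 ± 0.20), Mcm5 (0.73 ± 0.19) and Mcm3 (0.86 ± 0.23) in the authors' deposited table (adjusted p between 0.000552 and 0.00189).

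Of 24 rod genes with a p-value, 0 rose, 18 fell and 6 did not pass (1 rose and 21 fell adjusted over the list alone). Rod genes had a median log2 fold change of -0.45 (limma cameraPR, adjusted p = 9.02e-09). The calcium-binding protein gene Cabp4, the phosphodiesterase gene Pde6a and the ion exchanger gene Slc24a1 fell, at -0.71 ± 0.16 for Cabp4, -0.75 ± 0.22 for Pde6a and -0.76 ± 0.22 for Slc24a1 in the authors' deposited table (adjusted p between 0.000242 and 0.00579). Of 13 cone genes with a p-value, 0 rose, 9 fell and 4 did not pass (0 rose and 9 fell adjusted over the list alone). Cone genes had a median log2 fold change of -0.67 (limma cameraPR, adjusted p = 7.89e-06). Gnat2, the cone transducin, and Arr3, the cone arrestin, were among these, with -0.81 ± 0.22 for Gnat2 and -0.96 ± 0.28 for Arr3 in the authors' deposited table (adjusted p between 0.00254 and 0.00703). Of 14 photoreceptor precursor genes with a p-value, 1 rose, 9 fell and 4 did not pass (3 rose and 9 fell adjusted over the list alone). Photoreceptor precursor genes had a median log2 fold change of -0.37 (limma cameraPR, adjusted p = 0.00466). Rdh12, Aipl1 and Rpgrip1, which act in mature photoreceptors, led the falls, and Prdm1 was the member that rose. The authors' deposited table gives -0.55 ± 0.15 for Rdh12, -0.55 ± 0.16 for Aipl1, -0.51 ± 0.16 for Rpgrip1 and 0.43 ± 0.16 for Prdm1 (adjusted p between 0.00206 and 0.0328).

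Of 17 Müller glia genes with a p-value, 0 rose, 8 fell and 9 did not pass (0 rose and 9 fell adjusted over the list alone). Müller glia genes had a median log2 fold change of -0.34 (limma cameraPR, adjusted p = 6.34e-08). The potassium channel gene Kcnj10, the chaperone gene Clu and the water channel gene Aqp4 fell, at -0.81 ± 0.13 for Kcnj10, -1.25 ± 0.21 for Clu and -1.11 ± 0.19 for Aqp4 in the authors' deposited table (adjusted p between 1.37e-07 and 3.55e-07). Clu and Aqp4 also stood among the 10 largest falls of genes with a mean count at or above the median. The others were Adamts5, Epas1, Il33, Lrrc2, Myo5b, Wdr89, Chst3 and Fgf2. Their log2 fold changes lay between -1.32 and -1.01 in the authors' deposited table (adjusted p between 5.47e-10 and 0.00356). Beside glia and photoreceptors, blood vessel markers moved down. Of 11 blood vessel genes with a p-value, 0 rose, 3 fell and 8 did not pass (0 rose and 3 fell adjusted over the list alone). Blood vessel genes had a median log2 fold change of -0.57 (limma cameraPR, adjusted p = 0.000633). Flt1, Esam and Emcn fell, at -0.86 ± 0.21 for Flt1, -0.73 ± 0.23 for Esam and -0.75 ± 0.29 for Emcn in the authors' deposited table (adjusted p between 0.000999 and 0.0470). Of 14 immediate early and stress genes with a p-value, 0 rose, 4 fell and 10 did not pass (0 rose and 5 fell adjusted over the list alone). Immediate early and stress genes had a median log2 fold change of -0.13 (limma cameraPR, adjusted p = 0.0281, or 0.0816 with the correlation preset to 0.05). The heat shock genes Hspa1b and Hspa1a, near-identical copies whose reads are hard to assign, led these at -0.80 ± 0.21 for Hspa1b and -0.79 ± 0.21 for Hspa1a in the authors' deposited table (adjusted p between 0.00166 and 0.00272).

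Immune genes were higher beside the neuronal groups. Of 15 interferon response genes with a p-value, 12 rose, 0 fell and 3 did not pass (13 rose and 0 fell adjusted over the list alone). Interferon response genes had a median log2 fold change of 1.45 (limma cameraPR, adjusted p = 1.05e-17). Usp18, which removes an interferon-induced modifier from proteins, and the antiviral genes Rsad2 and Oas1a rose, at 3.10 ± 0.27 for Usp18, 1.88 ± 0.29 for Rsad2 and 1.90 ± 0.30 for Oas1a in the authors' deposited table (adjusted p between 4.47e-27 and 1.36e-08). Of 12 microglia genes with a p-value, 12 rose, 0 fell and 0 did not pass (12 rose and 0 fell adjusted over the list alone). Microglia genes had a median log2 fold change of 1.67 (limma cameraPR, adjusted p = 2.05e-26). Ctss, a lysosomal protease, the complement genes C1qc and C1qa and the chemokine receptor gene Cx3cr1 led them. The authors' deposited table gives 2.22 ± 0.20 for Ctss, 1.87 ± 0.24 for C1qc, 1.80 ± 0.25 for C1qa and 1.66 ± 0.23 for Cx3cr1 (adjusted p between 5.58e-25 and 1.01e-10), and mean counts of 581 for Ctss, 349 for C1qc, 358 for C1qa and 398 for Cx3cr1.

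Ctss, the macrophage gene Mpeg1 and the interferon-induced gene Ifi27 were also among the 10 largest rises of genes with a mean count at or above the median, with 2.31 ± 0.22 for Mpeg1 and 2.74 ± 0.26 for Ifi27 in the authors' deposited table (adjusted p between 2.25e-23 and 6.70e-23). After Pou3f1 and Ebf3, the others were the matrix protein gene Thbs1, the imprinted gene Peg10, Cd24a, a surface glycoprotein of immature neurons, the transcription factor gene Arnt2 and Parm1. They stood at 3.21 ± 0.24 for Thbs1, 2.55 ± 0.13 for Peg10, 2.53 ± 0.24 for Cd24a, 1.95 ± 0.17 for Arnt2 and 1.87 ± 0.18 for Parm1 in the authors' deposited table (adjusted p between 7.18e-81 and 4.01e-22).

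The other 12 lists did not pass at 14 days (limma cameraPR). Of 30 ganglion cell structure genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of -0.09 (adjusted p = 0.128). Of 8 ipsilateral genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 1 and 1 at an unadjusted p under 0.05), with a median of 0.03 (adjusted p = 0.971). Of 20 bipolar cell genes 3 rose and 3 fell (4 and 5 adjusted over the list alone), with a median of -0.05 (adjusted p = 0.808). Of 8 horizontal cell genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.09 (adjusted p = 0.582). Of 19 retinal progenitor genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.03 (adjusted p = 0.155). Of 25 synapse genes 6 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.04 (adjusted p = 0.276). Of 14 p53 and cell death genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of -0.03 (adjusted p = 0.807). Of 12 pigment epithelium genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.559). Of 16 lens genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.09 (adjusted p = 0.155). Of 8 red blood cell genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.606). Of 8 astrocyte and oligodendrocyte genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.469). Of 4 sex-linked genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05), with a median of -0.09 (adjusted p = 0.666). The median was negative while mean and test pointed up for the ganglion cell structure and p53 lists. For the ipsilateral list only the mean was negative, and for the bipolar list only the mean was positive.

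Single members of these lists changed. Among structure genes the RNA-binding protein gene Elavl2, the microtubule protein gene Dcx and the growth cone gene Gap43 rose, at 1.32 ± 0.22 for Elavl2, 1.44 ± 0.25 for Dcx and 0.99 ± 0.21 for Gap43 in the authors' deposited table (adjusted p between 9.60e-08 and 6.93e-05). Bipolar genes moved both ways, with 1.04 ± 0.19 for Bhlhe22 and -0.64 ± 0.20 for Lrit3 in the authors' deposited table (adjusted p between 1.54e-06 and 0.00956). The homeobox gene Six3, the Wnt antagonist gene Sfrp2, the synaptic gene Cplx2 and the horizontal cell gene Ndrg1 rose, and the p53 target gene Ccng1 fell. The authors' deposited table gives 0.69 ± 0.14 for Six3, 1.08 ± 0.29 for Sfrp2, 1.54 ± 0.22 for Cplx2, 0.38 ± 0.13 for Ndrg1 and -0.31 ± 0.07 for Ccng1 (adjusted p between 9.11e-10 and 0.0277). Markers of other cells that passed included Mitf of the pigment epithelium, the lens genes Crybb3, Cryba4 and Bfsp1, Hba-a1 of red blood cells and Mbp of oligodendrocytes. Their values were 0.80 ± 0.17 for Mitf, 0.83 ± 0.27 for Crybb3, 0.73 ± 0.27 for Cryba4, 0.63 ± 0.24 for Bfsp1, -0.79 ± 0.28 for Hba-a1 and 0.39 ± 0.10 for Mbp in the authors' deposited table (adjusted p between 0.000132 and 0.0467). Hba-a1 has a near-identical copy, so its value is uncertain.

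Both times were then set against each other, gene by gene. The fold change was higher at 14 days for microglia, interferon, contralateral, axon guidance and ganglion cell transcription factor genes, while Slitrk1, Slitrk5 and Ebf3 rose at both times. Of 14580 genes with an adjusted p at both times, 895 differed in a two-sided z test with Benjamini-Hochberg adjustment, 653 with the higher value at 14 days and 242 with the lower. Among genes called at both times 59 of 171 differed, including all 43 called in opposite directions. By limma cameraPR on that difference 14 lists were higher at 14 days. Median differences were 2.11 for microglia genes, 1.59 for interferon genes, 1.003 for contralateral genes and 0.50 for axon guidance genes (adjusted p = 9.57e-18, 8.16e-13, 2.07e-10 and 4.49e-10). The fold changes were shrunken toward 0 within each table, and the tables were normalized separately, which limits what a difference between them measures.

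Genes that rose at both times numbered 79, against 27.7 for independent lists (odds ratio 4.04, Fisher's exact test, two-sided, adjusted p = 1.98e-18). They included Slitrk1, Slitrk5, Alcam, Dock11, the transcription factor Tshz3, the imprinted gene Magel2, the collagen gene Col25a1 and the calcium release channel gene Ryr1. At 48 h those not given above stood at 1.99 ± 0.24 for Slitrk1, 2.49 ± 0.24 for Magel2, 1.24 ± 0.18 for Tshz3, 1.85 ± 0.29 for Col25a1 and 1.90 ± 0.28 for Ryr1 in the authors' deposited table. At 14 days the 8 stood at 1.39 ± 0.18 for Slitrk1, 1.37 ± 0.22 for Slitrk5, 1.57 ± 0.24 for Alcam, 2.06 ± 0.27 for Magel2, 1.31 ± 0.17 for Dock11, 1.58 ± 0.18 for Tshz3, 2.46 ± 0.25 for Col25a1 and 1.82 ± 0.30 for Ryr1 in the authors' deposited table. Genes that fell at both times numbered 49, against 21.9 (odds ratio 2.63, Fisher's exact test, adjusted p = 2.33e-07, or 0.0892 with calls at an adjusted p under 0.01). Among them were the neurotrophin receptor gene Ngfr, Synm, the stress gene Ddit4 and the metalloproteinase inhibitor gene Timp3. The authors' deposited table gives -0.87 ± 0.16 for Ngfr, -0.83 ± 0.17 for Ddit4 and -0.97 ± 0.23 for Timp3 at 48 h and -0.54 ± 0.11 for Ngfr, -0.51 ± 0.14 for Synm, -0.39 ± 0.10 for Ddit4 and -0.81 ± 0.19 for Timp3 at 14 days.

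For the 48 h rises that fell at 14 days (20 genes) and the 48 h falls that rose (23 genes), the overlap did not pass (odds ratios 0.961 and 0.760, Fisher's exact test, adjusted p = 1 and 0.278). With calls at an unadjusted p under 0.05 they passed, at 0.555 and 0.643 (adjusted p = 6.86e-08 and 1.74e-07). Among genes with a mean count at or above the median the first passed the other way, at 2.92 (adjusted p = 0.00211). Of its 20 genes 10 are encoded by mitochondrial DNA and 2 are pseudogenes. Without both classes, an alternative added after the data were seen, 8 remained against 18.0 (odds ratio 0.416, Fisher's exact test, adjusted p = 0.0175). Grik3 was of the latter kind, at -1.13 ± 0.19 at 48 h and 1.03 ± 0.18 at 14 days in the authors' deposited table. Across 14580 genes, which are not independent replicates, Spearman's rho of the fold changes was 0.132.

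**Figure D1:**
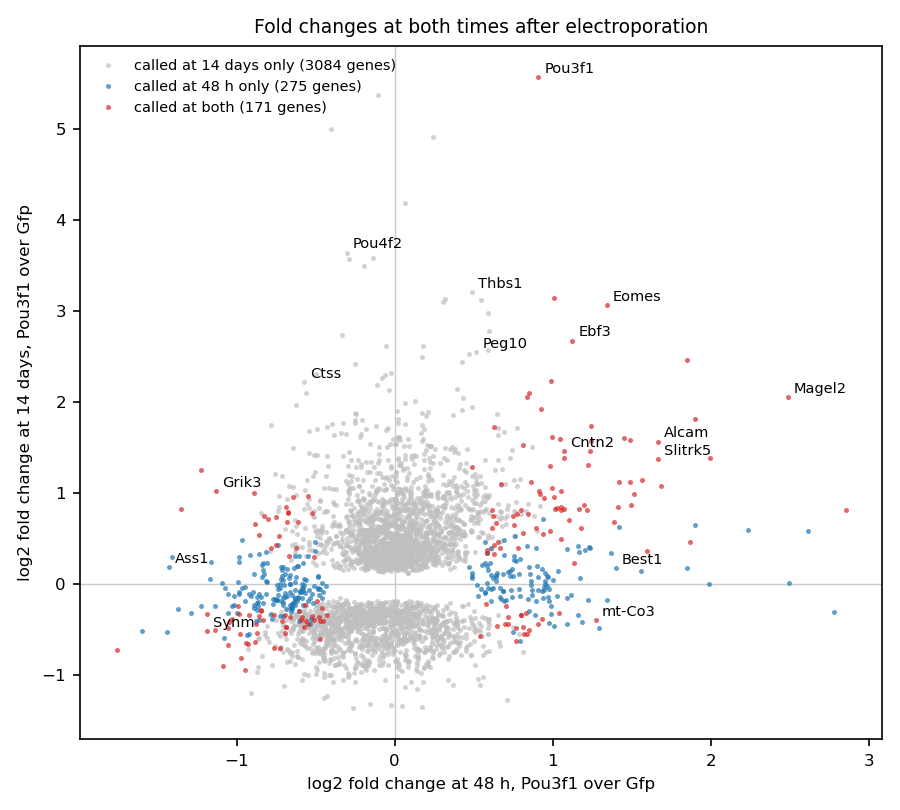
Log2 fold changes of Pou3f1 over Gfp cells at 48 h (horizontal) and at 14 days (vertical) in the authors' deposited tables, for genes called at both times (171), at 14 days only (3084) or at 48 h only (275), 1 point per gene. Pou3f1 lies at 0.91 and 5.57, and Eomes at 1.34 and 3.07.

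The E17.5 comparison asks what changes when Pou3f1 is lost from the embryonic retina. Amacrine and horizontal cell genes, axon guidance, synapse, contralateral and ganglion cell transcription factor genes were lower in the knockout than in the heterozygote. Cell cycle genes and, beside them, lens genes were higher. The table names no direction and was read as knockout over heterozygote because Pou3f1 is then lower in the knockout. The file's name puts the heterozygote first, which speaks for the opposite reading, so every E17.5 direction given here rests on that reading. Pou3f1 had a log2 fold change of -0.69, which is 1.61-fold lower in the knockout, in the authors' deposited table (adjusted p = 1.98e-08). Which part of the gene the knockout removes is not given in the labels. Of 14821 genes with an adjusted p, 1487 changed, 696 higher and 791 lower. Shifts of at least 2-fold numbered 31 higher and 26 lower.

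Of 18 amacrine genes with a p-value, 1 rose, 11 fell and 6 did not pass (1 rose and 11 fell adjusted over the list alone). Amacrine genes had a median log2 fold change of -0.47 (limma cameraPR, adjusted p = 3.77e-29). The AP-2 factor genes Tfap2a and Tfap2b and the GABA synthesis gene Gad1 were among those that fell. The authors' deposited table, which has no SE here, gives -1.18 for Tfap2a, -1.01 for Tfap2b and -1.36 for Gad1 (adjusted p between 3.03e-33 and 8.76e-13). Of 8 horizontal cell genes with a p-value, 0 rose, 5 fell and 3 did not pass (0 rose and 6 fell adjusted over the list alone). Horizontal cell genes had a median log2 fold change of -0.35 (limma cameraPR, adjusted p = 7.32e-13). Tfap2b and the vesicular GABA transporter gene Slc32a1, both also in the amacrine list, were among these 5. Slc32a1 stood at -0.93, Ndrg1 at -0.36 and the transcription factor Onecut1 at -0.36 in the authors' deposited table (adjusted p between 6.78e-09 and 0.000582). Of 25 synapse genes with a p-value, 0 rose, 11 fell and 14 did not pass (0 rose and 15 fell adjusted over the list alone). Synapse genes had a median log2 fold change of -0.24 (limma cameraPR, adjusted p = 3.41e-15). The neurexin gene Nrxn3, the active zone gene Rims1 and the vesicle gene Sv2a had the smallest adjusted p, at -1.02 for Nrxn3, -0.69 for Rims1 and -0.47 for Sv2a in the authors' deposited table (adjusted p between 2.24e-16 and 1.43e-05). Fold changes at E17.5 fell with transcript length (Spearman's rho -0.294 across genes, which are not independent replicates). With trends of length and GC content removed, an alternative added after the data were seen, synapse and axon guidance genes still passed (limma cameraPR, adjusted p = 9.48e-12 and 1.79e-07).

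Of 61 axon guidance genes with a p-value, 0 rose, 15 fell and 46 did not pass (0 rose and 19 fell adjusted over the list alone). Axon guidance genes had a median log2 fold change of -0.15 (limma cameraPR, adjusted p = 3.74e-13). The semaphorin receptor gene Plxna2, the semaphorin gene Sema5b, the ephrin receptor gene Ephb3 and the guidance cue gene Draxin fell, at -1.03 for Plxna2, -1.02 for Sema5b, -0.57 for Ephb3 and -0.43 for Draxin in the authors' deposited table (adjusted p between 2.50e-19 and 1.11e-05). Of 13 contralateral genes with a p-value, 0 rose, 4 fell and 9 did not pass (0 rose and 6 fell adjusted over the list alone). Contralateral genes had a median log2 fold change of -0.22 (limma cameraPR, adjusted p = 4.72e-06). Besides Pou3f1, Sox4, the semaphorin receptor gene Plxna1 and Cntn2 fell, at -0.57 for Sox4, -0.22 for Plxna1 and -0.33 for Cntn2 in the authors' deposited table (adjusted p between 1.68e-09 and 0.0344). Isl2, a transcription factor of contralateral cells, had -0.32 and did not pass in the authors' deposited table (adjusted p = 0.172).

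Of 37 ganglion cell transcription factors with a p-value, 3 rose, 10 fell and 24 did not pass (3 rose and 12 fell adjusted over the list alone). Ganglion cell transcription factors had a median log2 fold change of -0.16 (limma cameraPR, adjusted p = 4.72e-06). With Sox4, St18 (-0.94), Barhl2 (-0.70) and Myt1l (-0.52) fell with the smallest adjusted p in the authors' deposited table (adjusted p between 8.22e-18 and 0.000383). Of 11 POU family genes with a p-value, 1 rose, 3 fell and 7 did not pass (2 rose and 6 fell adjusted over the list alone). POU family genes had a median log2 fold change of -0.34 (limma cameraPR, adjusted p = 8.40e-05). Pou6f1 and Pou4f3 fell with Pou3f1 and Pou4f2 rose, at -0.70 for Pou6f1, -0.59 for Pou4f3 and 0.35 for Pou4f2 in the authors' deposited table (adjusted p between 8.63e-09 and 0.00554). Of 30 ganglion cell structure genes with a p-value, 1 rose, 5 fell and 24 did not pass (1 rose and 5 fell adjusted over the list alone). Ganglion cell structure genes had a median log2 fold change of -0.07 (limma cameraPR, adjusted p = 0.00572, or 0.0535 with the correlation preset to 0.05). The nicotinic receptor genes Chrnb3 and Chrna6 and the calretinin gene Calb2 fell, at -1.70 for Chrnb3, -0.57 for Chrna6 and -0.53 for Calb2 in the authors' deposited table (adjusted p between 1.65e-27 and 0.0117).

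Of 14 photoreceptor precursor genes with a p-value, 0 rose, 4 fell and 10 did not pass (0 rose and 5 fell adjusted over the list alone). Photoreceptor precursor genes had a median log2 fold change of -0.18 (limma cameraPR, adjusted p = 4.76e-05). They were the retinoid-binding protein gene Rbp3, the homeobox gene Otx2, Prdm1 and Aipl1, at -0.56 for Rbp3, -0.35 for Otx2, -0.34 for Prdm1 and -0.54 for Aipl1 in the authors' deposited table (adjusted p between 1.48e-05 and 0.0254). Of 12 cone genes with a p-value, 0 rose, 1 fell and 11 did not pass (0 rose and 4 fell adjusted over the list alone). Cone genes had a median log2 fold change of -0.22 (limma cameraPR, adjusted p = 0.000325). Gnb3 fell, at -0.51 in the authors' deposited table (adjusted p = 0.00275). Of 17 Müller glia genes with a p-value, 2 rose, 6 fell and 9 did not pass (2 rose and 6 fell adjusted over the list alone). Müller glia genes had a median log2 fold change of -0.08 (limma cameraPR, adjusted p = 0.000184). Hes1 is also a progenitor list gene, and a glial source was not tested. Crym and Kcnj10 fell and Dbi, an acyl-CoA binding protein, rose, at -1.02 for Crym, -1.08 for Kcnj10 and 0.47 for Dbi in the authors' deposited table (adjusted p between 1.54e-13 and 8.76e-07). Of 16 neurogenic progenitor genes with a p-value, 1 rose, 5 fell and 10 did not pass (1 rose and 5 fell adjusted over the list alone). Neurogenic progenitor genes had a median log2 fold change of -0.13 (limma cameraPR, adjusted p = 0.00145). Dll3, Insm1 and Olig2 fell and Atoh7 rose, at -0.46 for Dll3, -0.40 for Insm1, -0.48 for Olig2 and 0.35 for Atoh7 in the authors' deposited table (adjusted p between 9.97e-05 and 0.0133).

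Of 30 cell cycle genes with a p-value, 10 rose, 1 fell and 19 did not pass (13 rose and 1 fell adjusted over the list alone). Cell cycle genes had a median log2 fold change of 0.13 (limma cameraPR, adjusted p = 9.37e-09). Mcm3, the nucleotide synthesis gene Tyms and the replication clamp gene Pcna rose, at 0.34 for Mcm3, 0.43 for Tyms and 0.46 for Pcna in the authors' deposited table (adjusted p between 2.79e-07 and 8.58e-06). Genes of the lens, a tissue next to the retina, were higher beside them. Lim2 is listed under 2 identifiers, so the 18 lens genes make 19 entries, of which 13 rose, 0 fell and 6 did not pass (15 rose and 0 fell adjusted over the list alone). Lens genes had a median log2 fold change of 0.64 (limma cameraPR, adjusted p = 2.33e-27). The gamma-crystallin genes, structural proteins of the lens and near-identical copies of each other, included Crygf (2.00), Crygd (1.87) and Cryge (1.05) in the authors' deposited table (adjusted p between 1.34e-27 and 2.04e-07). Of 10 red blood cell genes with a p-value, 0 rose, 0 fell and 10 did not pass (0 rose and 0 fell adjusted over the list alone, and 2 higher and 0 lower at an unadjusted p under 0.05). Red blood cell genes had a median log2 fold change of 0.14 (limma cameraPR, adjusted p = 0.0131, or 0.0608 against random lists). Of 12 microglia genes with a p-value, 0 rose, 0 fell and 12 did not pass (0 rose and 2 fell adjusted over the list alone, and 0 higher and 3 lower at an unadjusted p under 0.05). Microglia genes had a median log2 fold change of -0.25 (limma cameraPR, adjusted p = 0.00190). Of 12 pigment epithelium genes with a p-value, 0 rose, 1 fell and 11 did not pass (0 rose and 1 fell adjusted over the list alone). Pigment epithelium genes had a median log2 fold change of -0.18 (limma cameraPR, adjusted p = 0.0452, or 0.1001 with the correlation preset to 0.05). Tyrp1 fell, at -0.56 in the authors' deposited table (adjusted p = 0.0184).

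Among the largest rises, genes with predicted names left out, were those 3 crystallins and 6 further genes. They are the histone gene H2ac15, the tectorin gene Tecta, the laminin gene Lama3, Rpl32l, annotated as a pseudogene of a ribosomal protein gene, Myh7b and the glutamate receptor gene Grm2. Their values were 2.05 for H2ac15, 1.96 for Tecta, 1.14 for Lama3, 1.09 for Rpl32l, 1.06 for Myh7b and 1.04 for Grm2 in the authors' deposited table (adjusted p between 3.66e-29 and 1.34e-07). Some genes with predicted names rose far more, such as Gm15459 (9.17) and Tdg-ps (5.77) in the authors' deposited table (adjusted p of 0 for both). After Chrnb3, the largest falls were those of Syt6, Abca13, Fezf1, Gad1, Dlg2, Srp54b, Tfap2a, Cpne4 and Spsb1. They lay between -1.54 and -1.16 in the authors' deposited table (adjusted p between 3.03e-33 and 1.82e-09). H2ac15, Rpl32l and Srp54b have near-identical copies, so their values are uncertain.

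The other lists did not pass at E17.5 (limma cameraPR). Of 8 ipsilateral genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05), with a median of -0.15 (adjusted p = 0.240). Of 24 rod genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.119). Of 20 bipolar cell genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), with a median of -0.07 (adjusted p = 0.176). Of 19 retinal progenitor genes 1 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of -0.02 (adjusted p = 0.118). Of 15 interferon genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 3 at an unadjusted p under 0.05), with a median of -0.15 (adjusted p = 0.0528). Of 14 p53 and cell death genes 0 rose and 0 fell (0 and 0 adjusted over the list alone and 0 and 1 at an unadjusted p under 0.05), with a median of 0.04 (adjusted p = 0.676). Of 14 immediate early and stress genes 2 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.157). Of 13 blood vessel genes 0 rose and 3 fell (0 and 3 adjusted over the list alone), with a median of -0.04 (adjusted p = 0.0669). Of 9 astrocyte and oligodendrocyte genes 0 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of -0.01 (adjusted p = 0.8004). The sex-linked list had 2 genes with a p-value, too few for the test, and 0 rose and 0 fell, with 0 and 0 adjusted over the list alone and 0 and 0 at an unadjusted p under 0.05 (median 0.02). For the progenitor list the median was negative while mean and test pointed up.

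Members of these lists that changed were the rod gene Esrrb, the bipolar genes Gpr179, Lhx4 and Bhlhe23 and the progenitor genes Sfrp2 and Hes1, with -0.54 for Esrrb, -0.55 for Gpr179, -0.41 for Lhx4, 0.51 for Bhlhe23, 0.96 for Sfrp2 and -0.19 for Hes1 in the authors' deposited table (adjusted p between 9.28e-39 and 0.0362). Fosb and Dusp1 were the early genes that rose and the heat shock gene Hspa1a fell, at 0.71 for Fosb, 0.25 for Dusp1 and -0.49 for Hspa1a in the authors' deposited table (adjusted p between 0.000876 and 0.0459). The vessel genes Cldn5, Kdr and Pdgfrb and the astrocyte gene Pax2 fell, at -0.68 for Cldn5, -0.31 for Kdr, -0.32 for Pdgfrb and -0.50 for Pax2 in the authors' deposited table (adjusted p between 4.84e-05 and 0.0362). How many libraries stand behind this table is uncertain, since 34 genes have a fold change and no p-value, which the default fit of the tool the labels name gives only with at least 3 libraries in a group.

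**Figure D2:**
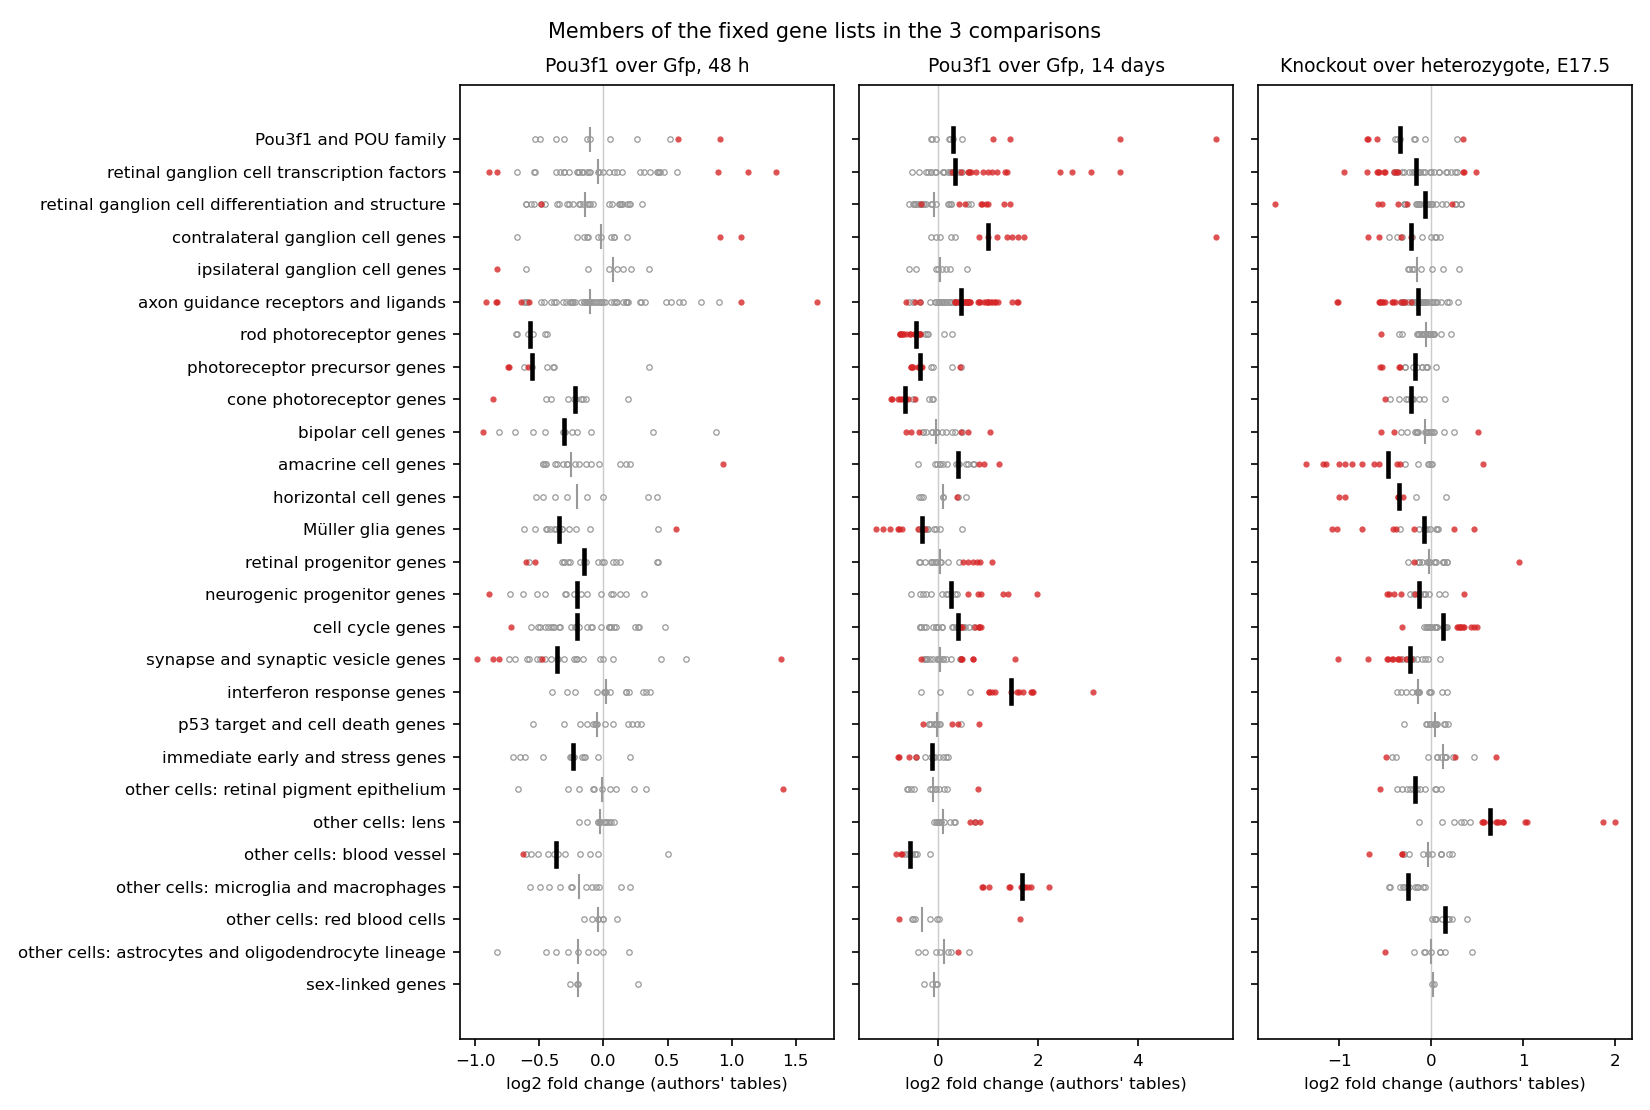
Log2 fold changes of the members of the 27 gene lists at 48 h, 14 days and E17.5 in the authors' deposited tables, 1 point per gene, filled red where the gene passed. Vertical bars mark each list's median, thick and black where cameraPR passed, which holds for 11 lists at 48 h, 15 at 14 days and 17 at E17.5.

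The last comparison asks whether genes that rise with added Pou3f1 fall when it is lost. At 14 days they did so more often than independent lists would, with Sox4 and Gad2 among them. Genes that rose at 14 days and fell in the knockout numbered 163, against 101 (odds ratio 1.85, Fisher's exact test, two-sided, adjusted p = 8.14e-10 over 12 overlaps). Others of them were the matrix proteoglycan gene Ncan, the protocadherin gene Pcdh8, the adhesion receptor gene Adgrl3, the G protein regulator gene Rgs4 and the fatty acid binding protein gene Fabp7. At 14 days these 5 had 1.09 ± 0.17 for Ncan, 0.76 ± 0.15 for Pcdh8, 0.83 ± 0.16 for Adgrl3, 1.31 ± 0.26 for Rgs4 and 1.29 ± 0.18 for Fabp7 in the authors' deposited table. At E17.5 the values were -0.68 for Ncan, -0.77 for Pcdh8, -0.87 for Gad2, -0.53 for Adgrl3, -0.97 for Rgs4 and -0.70 for Fabp7 in the authors' deposited table. Genes that fell at 14 days and rose in the knockout were fewer than independent lists would give, 40 against 63.4 (odds ratio 0.595, Fisher's exact test, adjusted p = 0.00270). This deficit was lost with calls at an adjusted p under 0.01 (odds ratio 0.955, adjusted p = 1) and among genes with a mean count at or above the median (0.756, adjusted p = 0.169).

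At 48 h the picture was another. Genes that rose at 48 h and fell in the knockout numbered 17, against 11.2 (odds ratio 1.57, Fisher's exact test, adjusted p = 0.116). Eomes, Slitrk1, the cortactin-binding gene Cttnbp2 and the protocadherin gene Pcdh7 were among them. The authors' deposited table gives 0.95 ± 0.22 for Cttnbp2 and 1.05 ± 0.22 for Pcdh7 at 48 h and -0.58 for Eomes, -0.53 for Slitrk1, -0.40 for Cttnbp2 and -0.28 for Pcdh7 at E17.5. Genes that fell at 48 h and rose in the knockout, Nkd1, Atoh7, Plekha2 and Mmp2, numbered 4 against 10.1 (odds ratio 0.382, Fisher's exact test, adjusted p = 0.0845). More genes moved the same way: 68 fell both at 48 h and in the knockout, against 12.1 (odds ratio 8.30, Fisher's exact test, adjusted p = 5.01e-32). Plxna2, Nrxn3, Kdr and Prdm1 were among these, picked from the fixed lists after their values were seen. Genes that rose in both numbered 19, against 9.35 (odds ratio 2.17, Fisher's exact test, adjusted p = 0.00677). Of these 9 are encoded by mitochondrial DNA and 2 are pseudogenes. In alternatives added after the data were seen the overlap did not pass without the former, with 10 against 8.74 (odds ratio 1.16, Fisher's exact test, adjusted p = 0.601). Nor did it without both, with 8 against 8.13 (odds ratio 0.983, adjusted p = 1). For 14 days the same-way overlaps did not pass, with 92 genes higher in both and 90 lower in both (Fisher's exact test, adjusted p = 0.405 and 0.116). Across genes, which are not independent replicates, Spearman's rho of the fold changes with E17.5 was 0.263 for 48 h over 14077 genes and -0.0165 for 14 days over 14555.

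**Figure D3:**
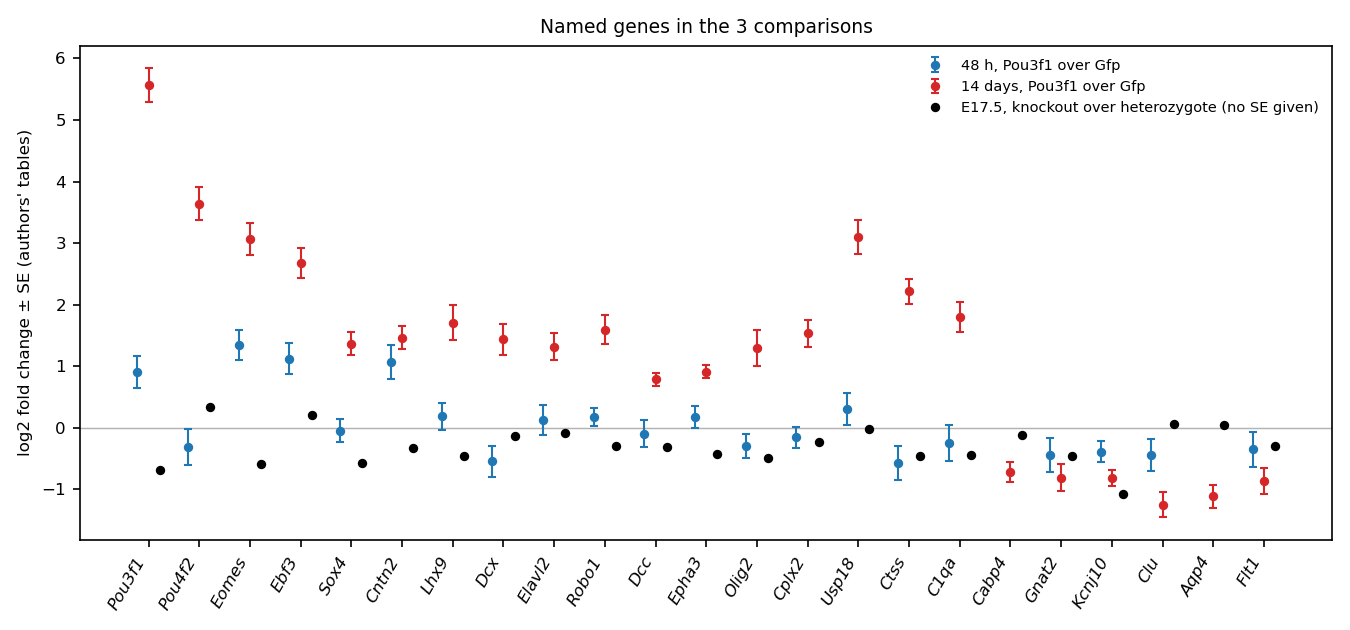
Log2 fold changes of named genes at 48 h (blue), 14 days (red) and E17.5 (black) in the authors' deposited tables, where bars are the authors' SE and the E17.5 table gives none. Sox4 stands at 1.37 ± 0.18 at 14 days and -0.57 at E17.5, and Kcnj10 at -0.81 ± 0.13 at 14 days and -1.08 at E17.5.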

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

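The comparison of times was planned, while tests of explanations for the microglia genes were chosen after the result was seen. Values are differences of shrunken log2 fold changes, 14 days minus 48 h, that passed their test. Unequal shrinkage as a source was not tested. Lists with a higher effect at 14 days differed by medians of 0.58 for POU family genes, 0.51 for ganglion cell transcription factor genes, 0.21 for ganglion cell structure genes, 1.003 for contralateral genes, 0.50 for axon guidance genes, 0.29 for photoreceptor precursor genes, 0.39 for bipolar genes, 0.57 for amacrine genes, 0.28 for retinal progenitor genes, 0.49 for neurogenic progenitor genes, 0.56 for cell cycle genes, 0.49 for synapse genes, 1.59 for interferon genes and 2.11 for microglia genes (limma cameraPR, adjusted p between 9.57e-18 and 0.0476).

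Named genes follow, from the authors' deposited tables, each with its planned z test of the difference. Differences of at least 2 were 4.67 for Pou3f1, 3.95 for Pou4f2, 3.07 for Ifi27, 2.81 for Mpeg1, 2.80 for Usp18, 2.80 for Ctss, 2.72 for Thbs1, 2.16 for Grik3, 2.11 for C1qc, 2.06 for C1qa, 2.06 for Cd24a and 2.03 for Peg10 (adjusted p between 1.21e-31 and 1.18e-05). Between 1.5 and 2 they were 2.00 for Cx3cr1, 1.98 for Dcx, 1.89 for Oas1a, 1.72 for Eomes, 1.70 for Rsad2, 1.69 for Cplx2, 1.62 for Ass1, 1.59 for Olig2, 1.55 for Ebf3, 1.53 for Pou3f2 and 1.53 for Lhx9 (adjusted p between 5.61e-08 and 0.00142). Smaller ones were 1.45 for Arnt2, 1.42 for Fabp7, 1.41 for Robo1, 1.41 for Sox4, 1.397 for Tfap2c, 1.28 for Rgs4, 1.24 for Sema5a, 1.23 for Nrxn3 and 1.22 for Parm1 (adjusted p between 9.08e-08 and 0.0233). Under 1.2 stood 1.19 for Elavl2, 1.18 for Prdm1, 1.10 for Pla2g7, 1.07 for Dll3, 1.07 for Ephb1, 1.04 for Irx3 and 1.003 for Gad2 (adjusted p between 5.87e-05 and 0.0405). The lowest positive ones were 0.97 for Rasgrf2, 0.94 for Irx6, 0.92 for Plxna2, 0.90 for Ndrg1, 0.88 for Dcc, 0.85 for Cplx3, 0.79 for Adgrl3, 0.74 for Epha3, 0.69 for Six3 and 0.66 for Mbp (adjusted p between 0.00187 and 0.0362). Lower at 14 days than at 48 h were -0.83 for Cttnbp2, -1.16 for Adamts5, -1.17 for Myo5b, -1.22 for Best1, -1.36 for mt-Nd1 and -1.67 for mt-Co3 (adjusted p between 1.38e-11 and 0.0436).

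The rise of microglia genes at 14 days was weighed further, since cells sorted for a plasmid's fluorescence should hold no microglia. A lower share of the main cell type alone would raise the markers of all other types, and blood vessel genes had a median log2 fold change of -0.57 at 14 days, which argues against it. A further set of 22 microglia genes, none in the first list, had a median of 1.07, with 18 of 22 called higher, so microglia or macrophages among the sorted cells may be the source. The further set had a median mean count of 85.1 at 14 days, 0 of 13 of its genes were called at 48 h, and at E17.5 0 were higher and 1 lower of 22. No microglia list gene stands in another fixed list, and a change of the transfected cells themselves, or of debris they take up, stays open and untested.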

How the results depend on the processing

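Alternatives that remove length and GC trends, pseudogenes, mitochondrially encoded genes or Pou3f1, keep E17.5 genes with adjusted p only, or adjust Pou3f1 over all genes were chosen after the data were seen. The called overlap of genes higher at 48 h and at E17.5 went from an odds ratio of 2.17 to 0.983 and did not pass without mitochondrially encoded genes and pseudogenes, 9 and 2 of its 19 genes, nor without the former alone (1.16). No other called result turned direction, but 3 uncalled overlaps did. That of genes higher at 48 h and lower at 14 days had an odds ratio of 0.961, and passed in opposite directions at an unadjusted p (0.555) and among abundant genes (2.92). It was 1.66 at an adjusted p under 0.01, and passed at 0.416 without these classes and at 0.483 without the former alone. Genes lower at 48 h and higher at 14 days, at 0.760, passed at an unadjusted p (0.643). The overlap of genes higher at 48 h and lower at E17.5 went from 1.57 to 0.857 at an unadjusted p. That of genes higher at 14 days and at E17.5 went from 1.11 to 0.957, 0.952 and 0.907 at an unadjusted p, an adjusted p under 0.01 and among abundant genes, and neither passed. Of 67 alternatives of main results 12 moved or crossed the threshold. The genes changed at 48 h fell to 230, the genes changed at 14 days to 2066 and the genes changed at E17.5 to 874 at an adjusted p under 0.01, and to 106, 496 and 57 at 2-fold or more, since fewer genes meet stricter limits. Genes differing between times numbered 441 at an adjusted p under 0.01. The deficit of genes lower at 48 h and higher at E17.5 passed at an unadjusted p (odds ratio 0.227) and among abundant genes (0.193). That of genes lower at 14 days and higher at E17.5 was lost at an adjusted p under 0.01 (0.955) and among abundant genes (0.756). Shared falls at 48 h and 14 days did not pass at an adjusted p under 0.01 (odds ratio 2.07). The cause was not tested for these odds ratios. Called lists ranged from 8 to 13 at 48 h, 13 to 16 at 14 days and 15 to 18 at E17.5, and 8 of 11, 13 of 15 and 14 of 17 kept their call in all 6 alternatives. Lost in at least 1 were cone, progenitor and cell cycle genes at 48 h, cell cycle and immediate early genes at 14 days, and ganglion cell structure, pigment epithelium and red blood cell genes at E17.5. Gained in at least 1 were ganglion cell structure, axon guidance, amacrine, microglia and astrocyte genes at 48 h, lens and red blood cell genes at 14 days, and ipsilateral, rod, interferon and immediate early genes at E17.5. Of 352 named gene values 11 crossed the threshold when adjusted over all genes. No paired analysis was possible because the tables hold no values per library, although groups share replicate numbers. For the same reason other normalizations and tools, pseudocounts, an analysis without a filter, robust dispersion, leaving out replicates, a replicate block, fry and an estimated correlation were not run, and what depth limits is known only from the SE.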

Other observations

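All gene families and tests here were chosen after the result was seen. Several families of neuronal surface proteins and transcription factors moved as groups, not all in the same direction. Slitrk genes, neuronal transmembrane proteins, had 3 higher and 0 lower of 6 (median 1.02, adjusted p = 4.57e-13) at 48 h. The same family had 3 higher and 0 lower of 6 (median 0.68, adjusted p = 0.000182) at 14 days and 0 higher and 3 lower of 6 (median -0.38, adjusted p = 0.000171) at E17.5 (limma cameraPR over the families of a comparison). Ebf transcription factor genes had 2 higher and 0 lower of 4 (median 0.73, adjusted p = 1.39e-07) at 48 h, 3 higher and 0 lower of 4 (median 1.03, adjusted p = 5.18e-09) at 14 days and 0 higher and 0 lower of 4 (median -0.01, adjusted p = 0.990) at E17.5 (limma cameraPR). Non-clustered protocadherin genes had 2 higher and 1 lower of 11 (median 0.36, adjusted p = 0.00649) at 48 h, 5 higher and 2 lower of 11 (median 0.48, adjusted p = 0.00196) at 14 days and 0 higher and 4 lower of 11 (median -0.25, adjusted p = 0.000322) at E17.5 (limma cameraPR). Clustered protocadherin genes went the other way at 48 h, with 0 higher and 1 lower of 57 (median -0.23, adjusted p = 3.86e-06), and had 6 higher and 1 lower of 58 (median 0.12, adjusted p = 0.0449) at 14 days and 1 higher and 14 lower of 58 (median -0.24, adjusted p = 1.00e-09) at E17.5 (limma cameraPR). At 14 days ephrin-A ligand genes had 4 higher and 0 lower of 5 (median 0.83, adjusted p = 0.00196) and kainate receptor genes 4 higher and 1 lower of 5 (median 0.68, adjusted p = 0.00905) (limma cameraPR). Neither passed at 48 h (adjusted p = 0.481 and 0.345) or E17.5 (0.883 and 0.137). AP-2 transcription factor genes had 0 higher and 0 lower of 5 (median -0.28, adjusted p = 0.0390) at 48 h, 1 higher and 0 lower of 5 (median 0.37, adjusted p = 0.149) at 14 days and 0 higher and 4 lower of 5 (median -0.75, adjusted p = 1.37e-21) at E17.5 (limma cameraPR).

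For the other families a technical source was not tested, and without values per library no other scaling was tried for any family. The 13 mRNAs encoded by mitochondrial DNA had 11 higher and 0 lower of 13 (median 0.81, adjusted p = 8.11e-36) at 48 h, 0 higher and 12 lower of 13 (median -0.44, adjusted p = 1.14e-08) at 14 days and 9 higher and 0 lower of 13 (median 0.61, adjusted p = 2.15e-28) at E17.5 (limma cameraPR). Cytosolic ribosomal protein genes, of which 3 are annotated as pseudogenes, had 0 higher and 0 lower of 81 (median 0.20, adjusted p = 5.63e-12) at 48 h, 5 higher and 0 lower of 83 (median 0.05, adjusted p = 0.0439) at 14 days and 61 higher and 0 lower of 82 (median 0.33, adjusted p = 6.02e-56) at E17.5 (limma cameraPR). Receptor genes of smell were slightly higher as groups at 48 h, with 1 higher and 0 lower of 528 (median 0.04, adjusted p = 0.00925) for olfactory and 1 higher and 0 lower of 195 (median 0.09, adjusted p = 0.000296) for vomeronasal receptor genes (limma cameraPR). At 14 days they were lower, with 1 higher and 42 lower of 443 (median -0.14, adjusted p = 0.000133) for olfactory and 0 higher and 35 lower of 188 (median -0.21, adjusted p = 1.23e-06) for vomeronasal receptor genes (limma cameraPR). Neither passed at E17.5 (adjusted p = 0.983 for both). Pseudogenes at 14 days counted 25 higher and 124 lower of 1334.

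Of 644 pseudogenes at E17.5, 66 were called higher (10.2%, against 4.44% of other genes, Fisher's exact p = 2.60e-09), 7 lower (1.09% against 5.53%, p = 9.27e-09), and most were uncalled. A uniform rise is argued against as the whole cause: the median of all 644 was 0.0290, and with it subtracted from each, 60 higher and 8 lower stayed past the largest called p (SE implied by fold change and p, binomial p = 5.75e-11). A segment of other strain origin around Pou3f1 is argued against as the whole cause, since 1 of 66 (1.52%) lie within 10 Mb of it. Genes there were called in 14.2% against 9.96% elsewhere (Fisher's exact p = 0.0288), so a part in the gene calls stays open. Segments elsewhere in the genome cannot be judged by this test, which looks only around Pou3f1. Reads shared with changed parent genes may account for part, since parents were called higher for 19 of 62 risen and 79 of 421 uncalled pseudogenes (odds ratio 1.91, Fisher's exact p = 0.0411; without ribosomal protein parents 2.06, p = 0.0988). Parents called lower were also more frequent, 5 of 62 against 5 of 421 (odds ratio 7.30, Fisher's exact p = 0.00451), no biological explanation was tested, and the rest stays open.

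Genes lower both at 48 h and at E17.5 were the other pattern weighed. A trend with transcript length and GC content is argued against as the whole cause: Spearman's rho across genes, which are not independent replicates, was 0.263 before and 0.196 after both were removed. Length itself had a rho with the fold change of -0.199 at 48 h and -0.294 at E17.5. A wrong reading of the direction of the E17.5 table cannot be told apart from a real shared response for these genes, because its direction rests on Pou3f1 alone, against the order of groups in the file's name, and both times disagree: at 48 h 87 shared genes moved the same way and 21 opposite ways, at 14 days 182 and 203, with an odds ratio of 1.85 for genes higher at 14 days and lower at E17.5. A biological difference between sorted postnatal cells and whole embryonic retinas stays open and was not tested.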
